A study of Mus musculus with 55 samples.

How the data were processed

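The deposited values are log2 signals that, per the submitters' processing notes, were made with GCRMA 2.2.0, which corrects background, normalises by quantiles and summarises probes into probe sets. The scanner software and all other upstream versions are not given in the sources used here. The range of the values, 0.2196 to 14.87, and the medians of the arrays, 2.554 to 2.612, are those of a log2 scale. The values were used as deposited.

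The table held 45101 probe sets, of which 34958 carried 1 gene symbol, 932 carried several and 9211 carried none. Probe sets without exactly 1 symbol were not used here. Of those with 1 symbol, 34754 had an Entrez identifier found in the gene table, and 0 symbols were changed by it. For each of 18193 genes the probe set with the highest mean over the 55 arrays was taken, a choice that mattered for 9012 genes with several probe sets. A gene was tested if it exceeded 20 on the linear scale in at least 3 arrays, which 8237 genes (45.28%) did. The Actb control probe sets were used for RNA quality only.

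Models were fitted in R 4.3.3 with limma 3.58.1, as 1 mean for each of 12 groups and a common variance for each gene, with 43 residual and 3.255 prior degrees of freedom. Each comparison was a contrast of these means, and p-values were adjusted by the method of Benjamini and Hochberg over all tested genes of that comparison. A gene was called at an adjusted p under 0.05, and fold counts use 1.5-fold. Gene lists were tested against all other tested genes by camera with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated from the residuals, and fry, were run beside it. Fry asks whether the genes of a list move, on balance, in 1 direction and does not compare them with other genes. RNA quality was compared by exact permutation tests. Correlations of changes among treatments that share controls were set beside those of 100 simulated draws without any effect.

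The comparisons, the gene lists, the thresholds and the rule for naming genes were chosen before the data were examined. The rule names 16 index genes in every treatment comparison. Among called genes whose treated arrays all lie on the same side of the control mean it names the 8 largest rises and 8 largest falls in each WT treatment and in KO against WT controls. It names 5 of each in each KO treatment and interaction (without the same-side condition in interactions), 3 of each between triglycerides, and up to 4 called members of each called list. Genes with only a clone or model name are counted but not named. Genes named outside the rule are marked in the text as chosen after their values were seen.

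The lists, with the number of members tested, covered PPAR targets (29), mitochondrial fatty acid oxidation (19), peroxisomal lipid metabolism (13), fatty acid uptake and lipid droplets (21), fatty acid synthesis and desaturation (14), cholesterol synthesis (12), LXR targets (7), NRF2 targets (22), amino acid and integrated stress response (10), unfolded protein response (12), heat shock (12), immediate early genes (16), the circadian clock (13), glucocorticoid responsive genes (15), FoxO targets and muscle atrophy (14), glucose metabolism (20), oxidative phosphorylation (19), hypoxia (11), inflammation (6), interferon response (9), fetal and stress genes (9), contractile genes (16) and extracellular matrix (13). The cell cycle list had 2 tested members and was not tested. Markers of endothelium (9), fibroblasts (9), smooth muscle (5), macrophages (9), brown adipocytes (3) and atrial muscle (4) were tested in the same way, and other marker sets with fewer than 3 bright members were not analysed here. 

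Independent genes were simulated at the group sizes and spread of these arrays, with 200 of 8237 changed. The model recovered 65.4%, 95.4% and 99.7% of log2 changes of 0.5, 1 and 2 for trilinolenin in WT hearts. It recovered 74.3%, 98.7% and 99.8% for trilinolenin in KO hearts and 43%, 89.6% and 99.5% for the Wy14643 interaction. The changed genes were drawn at random, so these shares need not hold for genes of wide spread or where fewer genes change. False calls were 4.72%, 5.95% and 5.85% of calls. Camera called the changed list in 10 of 10 draws and 0 of 190 unchanged lists, which does not test lists of correlated genes.

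The alternatives were no filter on dim genes, a filter at 100 on the linear scale (5204 genes), the mean of all probe sets of a gene, quantile normalization again, array weights, a trended and robust variance prior, the replicate number as a factor, a fit of only the groups compared, Spearman correlation, and each array left out in turn. Array weights ranged from 0.472 to 1.72. After the weights were seen, a fit without the 3 arrays of weight under 0.5 was added, and later the medians of called lists without each array.

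The labels give the age as both 9 to 12 weeks and 2 to 6 months. They give the control treatment as both none and carboxymethyl cellulose. Neither point enters the models.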

Results

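Gene expression was measured in the hearts of 55 male Sv129 mice, 1 Affymetrix mouse genome array per heart, so every value is the level of mRNA in whole heart tissue. The mice were wild type (WT, 25 arrays) or lacked the nuclear receptor PPARα (KO, 30 arrays), a fatty acid sensor that drives genes of fat oxidation. After a fast of 4 h each mouse received a single gavage of 400 µL and its heart was taken 6 h later. Per the treatment protocol the gavage held carboxymethyl cellulose alone (control, for which another label field reads none), the synthetic PPARα agonist Wy14643 in that vehicle, or 1 of 4 pure triglycerides. These were triolein, trilinolein, trilinolenin and tridocosahexaenoin, the triglycerides of oleic, linoleic, linolenic and docosahexaenoic acid. WT groups held 3 control, 4 triolein, 5 trilinolein, 4 trilinolenin, 5 tridocosahexaenoin and 4 Wy14643 hearts, and each KO group held 5. Of 18193 genes with a probe set of their own, 8237 were bright enough to be tested, exceeding 20 on the linear scale in at least 3 arrays. Where the mean of a group lies under that minimum, a log2 change against it is not exact, and such genes are named with the results. The median log2 value of an array lay between 2.55 and 2.61, between 29.0% and 30.2% of probe sets exceeded 20 on the linear scale, and array pairs correlated at 0.968 to 0.994. Errors of log2 changes are standard errors (SE), adjusted p-values come from limma, and the number of arrays, above all the 3 WT controls, limits their precision. No pair of arrays held more than 0.208% identical values. The labels describe each array as a heart of its own, and the p-values measure the spread between these hearts.

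Ppara, the targeted gene, was lower in KO than in WT control hearts by a log2 difference of -0.73 ± 0.13 (n = 5 and 3, adjusted p = 0.000132). Its 3 probe sets differed by -0.73, -1.29 and -0.71. On the probe set with the widest gap, 29 of 30 KO arrays lay below every WT array, and on the others 18 and 10 of 30 did. The position of these probe sets relative to the disrupted part of the gene was not used here, and a probe set outside that part checks nothing, so the remaining signal in KO hearts does not show transcript of the intact gene. The labels give WT and KO mice different substrains (129S1/SvImJ and 129S4/SvJae), so every difference between the genotypes below is one of genotype and substrain together.

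The comparison of KO with WT control hearts shows what the absence of PPARα goes with at baseline. Genes of fatty acid use were lower in KO hearts (n = 5) than in WT hearts (n = 3). Plin5, which coats lipid droplets in oxidative tissue, differed by a log2 value of -3.20 ± 0.21 (adjusted p = 1.01e-16). Acot1, a cytosolic acyl-CoA thioesterase, differed by -2.67 ± 0.35 and Ucp3, a mitochondrial carrier of the uncoupling protein family, by -2.03 ± 0.31. The KO means of Acot1 and Ucp3 lay under the brightness minimum, so their sizes are not exact. Of 19 genes of mitochondrial fatty acid oxidation 15 fell and 0 rose, among them Slc25a20, the carnitine-acylcarnitine carrier (-1.71 ± 0.09), Decr1 (-1.67 ± 0.07), Acot2 (-1.51 ± 0.19) and Cpt2 (-1.25 ± 0.07), while 17 fell when adjusted over the list alone. The median of the list was -0.53 and camera gave an adjusted p of 1.75e-60. Among 29 PPAR target genes 20 fell (23 when adjusted over the list alone, 1 rising), with a median of -0.53 and a camera adjusted p of 2.36e-57. Of the 13 tested peroxisomal genes 5 fell (6 adjusted over the list alone), namely Ech1 (-1.21 ± 0.07), Pex11a (-0.93 ± 0.12), Abcd3 (-0.87 ± 0.07), the catalase gene Cat (-0.72 ± 0.08) and, chosen after its values were seen, Hsd17b4 (-0.62 ± 0.09). These 3 lists share members, since 22 of the PPAR targets stand in another list and 11 of them in that of mitochondrial oxidation.

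Other metabolic genes differed between the control hearts as well. In fatty acid synthesis and desaturation Gpam, the first enzyme of glycerolipid synthesis, fell by 1.28 ± 0.08 and malic enzyme Me1 by 0.89 ± 0.09, 2 of 14 genes (3 adjusted over the list alone), with a camera adjusted p of 0.00059. Of 20 genes of glucose metabolism 5 rose (7 adjusted over the list alone), namely Pfkfb2 (0.76 ± 0.16), the glucose transporter Slc2a1 (0.54 ± 0.16), hexokinase Hk1 (0.45 ± 0.10), glycogen synthase Gys1 (0.39 ± 0.10) and, chosen after its values were seen, Slc2a4 (0.26 ± 0.07). Camera gave this list an adjusted p of 6.62e-06, against an adjusted p = 0.0515 with an estimated correlation. Of 21 genes of fatty acid uptake and lipid droplets 7 fell and 1 rose (9 and 4 adjusted over the list alone), among the falls Slc27a1 (-0.68 ± 0.14), Dgat2 (-0.69 ± 0.16) and Cidea (-0.65 ± 0.13). Its median was -0.0229 with a camera adjusted p of 0.00106, and the adjusted p was 0.267 with an estimated correlation. All 9 tested interferon response genes had higher means in KO hearts, with a median of 0.643, although none passed the test alone (camera adjusted p = 0.000806, adjusted p = 0.341 with an estimated correlation). This size is not exact, because in WT controls 4 of the 9 had means under the brightness minimum.

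In all, 298 genes differed between KO and WT control hearts, 128 higher and 170 lower in KO, 144 of them by over 1.5-fold. The largest falls also held Plaat1, a phospholipase and acyltransferase (-4.26 ± 0.18), Fah of tyrosine breakdown (-2.84 ± 0.21), the muscle fructose bisphosphatase Fbp2 (-2.71 ± 0.20), the galectin gene Lgals4 (-2.53 ± 0.17) and P3h4 (-2.17 ± 0.22). The largest rises were Lad1 (2.15 ± 0.27), Casq1, the calsequestrin of skeletal muscle (1.74 ± 0.26), Ndrg4 (1.70 ± 0.14), Tmprss13 (1.50 ± 0.30), Pigo (1.43 ± 0.15, with its 2 other bright probe sets at -0.334 and 0.23), the acyl-CoA synthetase Acsl6 (1.38 ± 0.16), Prkcq (1.33 ± 0.29) and Armcx4 (1.20 ± 0.24). The sizes for Plaat1, Fah, Fbp2, Lgals4 and P3h4 are not exact because their KO means lay under the brightness minimum, and those for Tmprss13 and Prkcq because their WT means did. Of the other index genes Pdk4, an inhibitory kinase of pyruvate dehydrogenase, fell by 0.93 ± 0.24, Cd36 by 0.27 ± 0.06 and Fabp3 by 0.25 ± 0.04, and Angptl4, an inhibitor of lipoprotein lipase, differed by 1.11 ± 0.44 without passing the test (adjusted p = 0.211). Without WT control replicate 2 the count was 193, and with only these groups in the fit it was 190. Averaged over all 6 treatments, 3211 genes differed between the genotypes, 295 of the 298 among them with the same sign.

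Triolein, with 1 double bond in each fatty acid, changed few genes in WT hearts. Angptl4 rose by 2.32 ± 0.46 (n = 4 against 3, adjusted p = 0.0245), with replicate 3 at 9.461 and the other hearts at 7.853 to 8.023. Hsd17b11, a dehydrogenase found on lipid droplets, rose by 0.64 ± 0.12 and the endothelial transcription factor gene Sox18 by 0.64 ± 0.14. Nabp1 fell by 0.82 ± 0.16, the cationic amino acid transporter Slc7a1 by 0.71 ± 0.15 and Slc25a13, the mitochondrial aspartate-glutamate carrier, by 0.34 ± 0.07. Ucp3 differed by 1.44 ± 0.32 (adjusted p = 0.0587), with replicate 3 at 7.827 and the others at 7.19 to 7.222, and Acot1 by 1.12 ± 0.36 (adjusted p = 0.448). As a group the 29 PPAR target genes rose, with a median of 0.205, 26 members above 0 and 7 called when adjusted over the list alone (camera adjusted p = 3.73e-16). Smooth muscle markers (median 0.737, 3 of 5 called adjusted over the list alone) and atrial markers (1.5) were higher in the same hearts. Their adjusted p was 0.15 and 0.23 with an estimated correlation. Genes of fatty acid uptake and lipid droplets (median 0.19), peroxisomal lipid metabolism (0.113) and FoxO targets and muscle atrophy (0.102) rose by camera. Their adjusted p was 0.0972, 0.112 and 0.646 with an estimated correlation. Camera also called mitochondrial oxidation (0.0298, median -0.00011 without WT control replicate 3), and glucose metabolism fell (-0.064). Both had an adjusted p = 0.386 with an estimated correlation. In total 6 genes were called, 3 in each direction, and 527 genes had an unadjusted p under 0.05 where 411.8 would by chance. The count was 0 without WT control replicate 1 or 3 or triolein replicate 3 or 4, 3 without triolein replicate 2 and 10 without triolein replicate 1.

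Trilinolein, with 2 double bonds in each fatty acid, was compared with the control gavage in WT hearts (n = 5 against 3). Angptl4 rose by 2.17 ± 0.44 (adjusted p = 0.00743) and Ucp3 by 1.29 ± 0.31 (adjusted p = 0.0241). Other rises were in Dixdc1 (1.09 ± 0.29), the interferon-induced GTPase gene Iigp1 (1.00 ± 0.17), Abhd1 (0.96 ± 0.18), Etfbkmt, a methyltransferase of the electron transfer flavoprotein (0.95 ± 0.12, adjusted p = 4.02e-06), Slc46a3 (0.92 ± 0.23) and Art5 (0.89 ± 0.19). The largest falls were in Nr4a1, an orphan receptor gene of the immediate early class (-1.78 ± 0.46), and Nppb, which encodes the B-type natriuretic peptide (-1.66 ± 0.36). They were followed by Slc41a3 (-1.11 ± 0.26), Nabp1 (-1.10 ± 0.15), Tmtc2 (-1.05 ± 0.19), the desaturase gene Scd2 (-0.94 ± 0.20), Tnfaip2 (-0.94 ± 0.22) and Ung (-0.73 ± 0.17). PPAR target genes rose as a group (median 0.249, 3 called including Cpt2 at 0.26 ± 0.07, and 10 when adjusted over the list alone), with an adjusted p = 0.095 with an estimated correlation. In the NRF2 list Mgst1 (0.63 ± 0.11) and Osgin1 (0.51 ± 0.12) rose, and the list rose by camera with a median of 0.0933 (adjusted p = 0.307 with an estimated correlation). FoxO targets rose (median 0.343, only Fbxo32 called at 0.38 ± 0.09, 7 adjusted over the list alone), and immediate early genes fell (median -0.454). The adjusted p was 0.119 and 0.594 with an estimated correlation. In mitochondrial oxidation Cpt2 and Eci2 (0.25 ± 0.05) rose, and in lipid uptake the hormone-sensitive lipase gene Lipe did (0.64 ± 0.16). Camera also called rises of lipid droplets (median 0.169) and peroxisomal genes (0.141), both at an adjusted p = 0.119 with an estimated correlation. It called a rise of mitochondrial oxidation (0.0392) and a fall of glucose metabolism (-0.062), both at an adjusted p = 0.385 with an estimated correlation, but the former was -0.00625 without WT control replicate 3. The means of Dixdc1 and Osgin1 in controls and of Tmtc2 after trilinolein lay under the brightness minimum. In total 103 genes were called, 44 up and 59 down, 43 by over 1.5-fold. Without single arrays the count fell to 16 (WT control replicate 3), 31 (WT control replicate 2), 47 (trilinolein replicate 5), 50 (replicate 3) and 53 (replicate 2).

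Trilinolenin, with 3 double bonds in each fatty acid, had the highest count among the WT treatments (n = 4 against 3). Hmox1, the inducible heme oxygenase, rose by 2.84 ± 0.68 (adjusted p = 0.0133). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 1.81 ± 0.43, Angptl4 by 1.76 ± 0.46, and the metallothionein gene Mt2 by 1.56 ± 0.36. So did the zinc finger gene Zbtb16 by 1.50 ± 0.39, Fam214a by 1.39 ± 0.30, Ucp3 by 1.31 ± 0.32 and Dixdc1 by 1.27 ± 0.30. Nr4a1 fell by 2.13 ± 0.48 (adjusted p = 0.00997), the cardiac growth factor gene Fgf16 by 1.49 ± 0.35, and Tnfrsf12a by 1.32 ± 0.34. Nppb fell by 1.29 ± 0.38, the heat shock gene Dnajb1 by 1.17 ± 0.27, the clock gene Ciart by 1.14 ± 0.32, Slc35e2 by 1.00 ± 0.23 and Dapp1 by 1.00 ± 0.27. In fatty acid uptake and lipid droplets 5 of 21 genes rose (8 rose and 1 fell adjusted over the list alone), Angptl4 with Lipe (0.73 ± 0.17), Plin4 (0.60 ± 0.16), Plin2 (0.55 ± 0.14) and, chosen after its values were seen, Slc27a1 (0.54 ± 0.14). Of 22 NRF2 targets 4 rose (6 adjusted over the list alone), Hmox1 with the glutathione transferase genes Gsta3 (1.22 ± 0.33) and Mgst1 (0.62 ± 0.12) and with Osgin1 (0.54 ± 0.13). Of 14 FoxO and atrophy genes 5 rose (11 adjusted over the list alone), namely Gabarapl1 (0.77 ± 0.19), Bnip3 (0.66 ± 0.16), Sesn1 (0.56 ± 0.13), Ccng2 (0.52 ± 0.15) and, chosen after its values were seen, the ubiquitin ligase gene Fbxo32 (0.44 ± 0.09). Camera called these lists, the PPAR targets (median 0.146) and the glucocorticoid responsive genes (median 0.413, 4 of 15 called). With an estimated correlation the adjusted p was 0.0956 for lipid droplets, 0.217 for NRF2, 0.0644 for FoxO, 0.0882 for PPAR and 0.385 for glucocorticoid genes. Camera also called a rise of mitochondrial oxidation (median 0.0125, -0.0187 without WT control replicate 3) and a fall of glucose metabolism (-0.0641). Their adjusted p was 0.607 and 0.518 with an estimated correlation. The means of Dixdc1 and Osgin1 in controls, of Ciart and Slc35e2 after trilinolenin and of Dapp1 in both groups lay under the brightness minimum. In total 281 genes were called, 118 up and 163 down, 121 by over 1.5-fold. The count was 46, 126 and 149 without WT control replicates 2, 3 and 1, and 160, 164 and 183 without trilinolenin replicates 2, 4 and 3.

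Tridocosahexaenoin, with longer chains and 6 double bonds in each, was compared with the control gavage in WT hearts (n = 5 against 3). Fkbp5 rose by 2.04 ± 0.41 (adjusted p = 0.00869), Zbtb16 by 1.64 ± 0.37 and Mt2 by 1.32 ± 0.34, with Cnksr1 (1.30 ± 0.33), Rasgef1b (1.23 ± 0.34), Ifi207 (1.10 ± 0.29), Maff (1.08 ± 0.27) and Rnf144b (1.04 ± 0.26). Fgf16 fell by 1.58 ± 0.33, Lrrc3b by 1.14 ± 0.22, Magi3 by 0.96 ± 0.20 and Tmtc2 by 0.95 ± 0.19. Ppargc1b, a coactivator of mitochondrial genes, fell by 0.94 ± 0.21, Tnfaip2 by 0.93 ± 0.22, Arhgap18 by 0.85 ± 0.22 and Carns1 by 0.84 ± 0.22. Of 15 glucocorticoid responsive genes 5 rose (6 adjusted over the list alone), the fifth, Mt1 (0.72 ± 0.18), being named after its values were seen, beside Klf15 at 0.80 ± 0.22. The median of that list was 0.724, and the adjusted p was 0.125 with an estimated correlation. Of 14 FoxO and atrophy genes 5 rose (8 adjusted over the list alone), among them Gabarapl1 (0.78 ± 0.18), Sesn1 (0.69 ± 0.12), Bnip3 (0.58 ± 0.15) and, named after its values were seen, Trim63 (0.33 ± 0.09). Angptl4 differed by 0.30 ± 0.44 (adjusted p = 0.825), Ucp3 by 0.19 ± 0.31 (adjusted p = 0.843), and the PPAR list by a median of 0.0635 (camera adjusted p = 0.0203, adjusted p = 0.511 with an estimated correlation). Without WT control replicate 3 these were -0.06, -0.22 and 0.0101, and without tridocosahexaenoin replicate 4 they were 0.60, 0.51 and 0.124. That replicate read 5.111 for Angptl4 and 4.848 for Ucp3, below the other 4. Hmox1, named after its values were seen because not all arrays lay on 1 side of the control mean, rose by 2.68 ± 0.65 (adjusted p = 0.0253). Smaller list shifts were those of amino acid and integrated stress response genes (median 0.187), the unfolded protein response (0.0661, Herpud1 called at 0.95 ± 0.20) and lipid droplets (0.0594, Plin4 called at 0.72 ± 0.15). Their adjusted p was 0.125, 0.501 and 0.374 with an estimated correlation. The means of Maff in controls and of Tmtc2 and Arhgap18 after tridocosahexaenoin lay under the brightness minimum. In total 153 genes were called, 63 up and 90 down, 68 by over 1.5-fold. The count was 0 and 12 without WT control replicates 2 and 1, 10, 33 and 250 without tridocosahexaenoin replicates 5, 3 and 4, and 13 with only these groups in the fit.

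Wy14643, the synthetic agonist, was compared with its vehicle in WT hearts (n = 4 against 3). Angptl4 rose by 2.17 ± 0.46 (adjusted p = 0.0409), Acot1 by 1.93 ± 0.36 (adjusted p = 0.0122), Abhd1 by 1.02 ± 0.19 and Mlycd, the malonyl-CoA decarboxylase, by 0.78 ± 0.16, while Frem2 fell by 0.82 ± 0.16, with means under the brightness minimum in both groups. These 5 were all the genes called, and 3 of 35 splits of the same arrays called as many. Ucp3 differed by 1.36 ± 0.32 (adjusted p = 0.0702), Pdk4 by 0.87 ± 0.25 (adjusted p = 0.219) and Cpt1a by 0.07 ± 0.19 (adjusted p = 0.97). PPAR target genes rose as a group by a median of 0.206, with 12 of 29 called when adjusted over the list alone and a camera adjusted p of 5.42e-19. Smooth muscle markers were higher in the same hearts (median 0.677, camera adjusted p = 0.0169, adjusted p = 0.378 with an estimated correlation). Camera also called peroxisomal genes (median 0.143, adjusted p = 0.144 with an estimated correlation), mitochondrial oxidation (0.0686), lipid droplets (0.0689) and FoxO targets (0.293), each at an adjusted p = 0.272 with an estimated correlation. Glucocorticoid responsive genes (0.181), immediate early genes (0.203) and heat shock genes (0.0532) were called too, at an adjusted p = 0.444, 0.444 and 0.522 with an estimated correlation. An unadjusted p under 0.05 was reached by 614 genes. The count of 5 went to 0 without WT control replicate 1 or 3 or Wy14643 replicate 4, to 9 without WT control replicate 2, and to 8 and 16 without Wy14643 replicates 3 and 1. It was 41 with array weights.

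**Figure D1:**
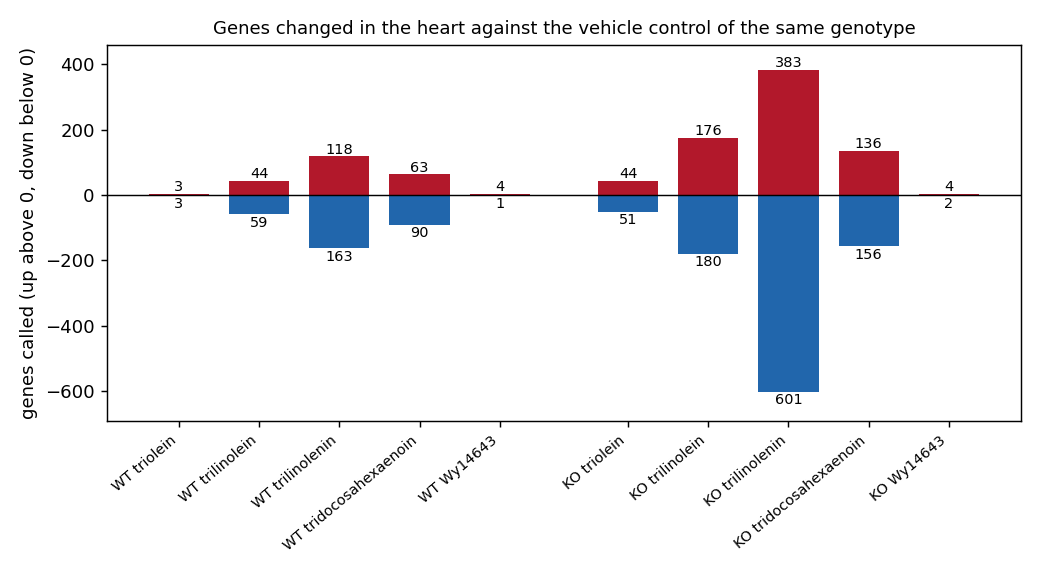
Number of genes called against the control of the same genotype (y axis, genes higher in treated hearts above 0 and lower ones below 0) for each treatment of WT and KO mice (x axis). Trilinolenin has the highest count in each genotype, 281 genes in WT and 984 in KO, and Wy14643 calls 5 and 6.

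In KO hearts the same treatments were set against 5 KO controls to ask what they change without PPARα. Triolein raised Zbtb16 by 1.52 ± 0.32 (n = 5 against 5, adjusted p = 0.0151), Fkbp5 by 1.49 ± 0.35, Fam107a by 1.38 ± 0.32, Rtp4 by 1.36 ± 0.36 and Rasgef1b by 1.27 ± 0.29. Tfrc, the transferrin receptor of iron uptake, fell by 1.23 ± 0.33, Fam78a by 0.95 ± 0.22, Trim7 by 0.86 ± 0.22, Dnajb1 by 0.85 ± 0.23 and Pik3r3 by 0.75 ± 0.19. Interferon response genes rose by a median of 0.982, with Rtp4, Usp18 (1.18 ± 0.24) and the antiviral gene Rsad2 (0.90 ± 0.21) called among 9, and 8 called when adjusted over the list alone (camera adjusted p = 1.52e-10, adjusted p = 0.117 with an estimated correlation). Macrophage markers were higher in the same hearts (median 0.205, 8 of 9 above 0, camera adjusted p = 0.00341, adjusted p = 0.45 with an estimated correlation). Glucocorticoid responsive genes (median 0.471), FoxO targets (0.295) and lipid droplets (0.141) rose, and glucose metabolism (-0.0838) and oxidative phosphorylation (-0.0405) fell, each at an adjusted p = 0.207 with an estimated correlation. PPAR targets (0.0769) rose and cardiac contractile genes (-0.0381) fell, both at an adjusted p = 0.516 with an estimated correlation. The means of Usp18 in controls and of Trim7 in both groups lay under the brightness minimum. In total 95 genes were called, 44 up and 51 down, 34 by over 1.5-fold. The count was 15, 15, 8, 41 and 201 without KO control replicates 1 to 5 in turn, 10, 4 and 5 without triolein replicates 3, 4 and 5, 31 with only these groups in the fit and 391 with array weights.

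Trilinolein in KO hearts raised Hmox1 by 2.23 ± 0.56 (n = 5 against 5, adjusted p = 0.0157), Zbtb16 by 1.66 ± 0.32, Fkbp5 by 1.65 ± 0.35, Mt2 by 1.45 ± 0.30 and the kinase gene Map3k6 by 1.31 ± 0.32. Tfrc fell by 1.77 ± 0.33, the apelin receptor gene Aplnr by 1.75 ± 0.51, Tmprss13 by 1.32 ± 0.26, the metalloprotease gene Adam19 by 1.23 ± 0.32 and Akr1c14 by 1.12 ± 0.26. Pdk4 rose by 1.03 ± 0.20 (adjusted p = 0.00246). Of 22 NRF2 targets 4 rose (8 adjusted over the list alone), Hmox1 with Gsta3 (1.15 ± 0.27), Gclm of glutathione synthesis (0.97 ± 0.25) and Mgst1 (0.42 ± 0.10), at an adjusted p = 0.145 with an estimated correlation. Of 13 extracellular matrix genes the collagen genes Col3a1 (-0.82 ± 0.20), Col1a1 (-0.78 ± 0.20), Col4a1 (-0.37 ± 0.11) and Col4a2 (-0.30 ± 0.09) fell, and the list fell by a median of -0.159 (adjusted p = 0.21 with an estimated correlation). Of 15 glucocorticoid responsive genes 8 rose (11 adjusted over the list alone, median 0.673), and of 14 FoxO genes 7 did (11 adjusted over the list alone, median 0.381). The adjusted p was 0.136 and 0.0998 with an estimated correlation. Among lipid droplet genes Dgat2 (0.61 ± 0.14), Plin4 (0.60 ± 0.13), Gpihbp1 (0.58 ± 0.12) and Lipe (0.58 ± 0.14) rose (list median 0.244, adjusted p = 0.145 with an estimated correlation). Heat shock genes (-0.136, Dnajb1 at -0.92 ± 0.23) and oxidative phosphorylation (-0.0383) fell and interferon genes (0.378) rose by camera, each at an adjusted p = 0.508 with an estimated correlation. The means of Map3k6 and Gsta3 in controls and of Tmprss13 after trilinolein lay under the brightness minimum. In total 356 genes were called, 176 up and 180 down, 126 by over 1.5-fold. The count was 218, 160 and 233 without KO control replicates 2, 3 and 4, and 213 and 100 without trilinolein replicates 1 and 4.

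Trilinolenin in KO hearts gave the largest response of the 10, with 984 genes called, 383 up and 601 down, 285 by over 1.5-fold. Hmox1 rose by 3.04 ± 0.56 (n = 5 against 5, adjusted p = 0.000299), the histone methyltransferase gene Setdb2 by 2.18 ± 0.57, Zbtb16 by 2.14 ± 0.32, Fkbp5 by 1.90 ± 0.35 and Mt2 by 1.87 ± 0.30. The largest falls were in Aplnr (-2.76 ± 0.51), Tfrc (-1.76 ± 0.33), the transcription factor gene Sox4 (-1.47 ± 0.29), Fgf16 (-1.36 ± 0.29) and Adam19 (-1.34 ± 0.32). Of 15 glucocorticoid responsive genes 12 rose (13 adjusted over the list alone) with a median of 0.853, among them the cell cycle inhibitor gene Cdkn1a (1.85 ± 0.47), and 13 of 14 FoxO and atrophy genes rose with a median of 0.523, including Klf15 (0.85 ± 0.19), Gabarapl1 (0.79 ± 0.16) and Bnip3 (0.65 ± 0.13). Of 22 NRF2 targets 7 rose (9 rose and 1 fell adjusted over the list alone), with Gsta3 at 1.28 ± 0.27, Gclm at 0.99 ± 0.25 and Aox1 at 0.43 ± 0.14 (median 0.127, adjusted p = 0.37 with an estimated correlation). Pdk4 rose by 1.05 ± 0.20 and Angptl4 by 1.17 ± 0.38, and 7 of 21 lipid droplet genes rose and 1 fell, with Plin4 at 0.71 ± 0.13 and Gpihbp1 at 0.64 ± 0.12 (median 0.242, adjusted p = 0.367 with an estimated correlation). Mitochondrial oxidation fell slightly (median -0.098, with Acaa2 at -0.27 ± 0.07, Acadvl at -0.18 ± 0.05 and Acadl at -0.12 ± 0.04, adjusted p = 0.42 with an estimated correlation). Glucose metabolism (-0.0863) and oxidative phosphorylation (-0.0564, Uqcrfs1 called at -0.12 ± 0.03) fell by camera, both at an adjusted p = 0.407 with an estimated correlation. In glucose metabolism Pfkfb2 (-0.53 ± 0.14), Slc16a1 (-0.27 ± 0.06) and Pkm (-0.16 ± 0.05) fell and Slc2a1 rose (0.55 ± 0.14). Interferon genes had a median of 0.414 (camera adjusted p = 0.0128, adjusted p = 0.491 with an estimated correlation) with 0 of 9 called by limma, also when adjusted over the list alone. The list mean was 6.28 and 6.24 in replicates 2 and 5, 4.85, 5.36 and 4.62 in replicates 1, 3 and 4, and 4.63 to 5.22 in KO controls. The means of Setdb2 and Gsta3 in controls and of Fgf16 after trilinolenin lay under the brightness minimum. The count was 649 without KO control replicate 3 and 633 with only these groups in the fit.

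Tridocosahexaenoin in KO hearts raised Zbtb16 by 1.99 ± 0.32 (n = 5 against 5, adjusted p = 0.000537), Fkbp5 by 1.94 ± 0.35, Map3k6 by 1.49 ± 0.32, and the cytochrome P450 genes Cyp2e1 by 1.49 ± 0.42 and Cyp1b1 by 1.47 ± 0.24. Aplnr fell by 1.94 ± 0.51, Tfrc by 1.19 ± 0.33, Nrep by 1.14 ± 0.24, Fam78a by 1.09 ± 0.22 and S1pr3 by 1.08 ± 0.27. Stress response genes rose, with Chac1, which degrades glutathione, at 1.18 ± 0.23 and Slc3a2 at 0.37 ± 0.09 in the amino acid list (median 0.109). Herpud1 rose by 0.77 ± 0.17 and Edem1 by 0.46 ± 0.12 in the unfolded protein list (median 0.141, -0.0232 without tridocosahexaenoin replicate 1). The lists had an adjusted p = 0.119 and 0.411 with an estimated correlation. Of 15 glucocorticoid responsive genes 7 rose (11 adjusted over the list alone, median 0.625), including Mt2 at 1.20 ± 0.30, and of 14 FoxO genes 4 rose (8 adjusted over the list alone, median 0.356), Klf15 (0.72 ± 0.19), Foxo3 (0.48 ± 0.13), Bnip3 (0.47 ± 0.13) and Sesn1 (0.40 ± 0.11). Both lists had an adjusted p = 0.119 with an estimated correlation. Pdk4 rose by 0.77 ± 0.20, Plin4 by 0.68 ± 0.13, Lipe by 0.49 ± 0.14 and Gpihbp1 by 0.47 ± 0.12, and the cytokine signalling inhibitor gene Socs3 by 1.06 ± 0.28. Camera also called lipid droplets (0.132) and inflammation (0.239, 1 of 6 genes), both at an adjusted p = 0.158 with an estimated correlation. Camera called falls of glucose metabolism (-0.0758, Pgam2 at -0.20 ± 0.05) and oxidative phosphorylation (-0.0391), both at an adjusted p = 0.347 with an estimated correlation, and of mitochondrial oxidation (-0.0727, adjusted p = 0.503 with an estimated correlation). The means of Map3k6, Cyp2e1 and Chac1 in controls lay under the brightness minimum. In total 292 genes were called, 136 up and 156 down, 107 by over 1.5-fold. The count was 179, 161 and 90 without KO control replicates 1, 2 and 3, and 194, 505 and 43 without tridocosahexaenoin replicates 3, 4 and 5. It was 12 with only these groups in the fit, and 93 without the 3 arrays of lowest weight (tridocosahexaenoin replicates 1 and 5 and trilinolenin replicate 5), a choice made after the weights were seen.

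Wy14643 in KO hearts raised Zbtb16 by 1.71 ± 0.32 (n = 5 against 5, adjusted p = 0.0225), Fam107a by 1.49 ± 0.32, the metalloprotease inhibitor gene Timp4 by 0.67 ± 0.14 and Rhobtb1 by 0.57 ± 0.12. Myorg fell by 0.78 ± 0.16, with means under the brightness minimum in both groups, and Cxxc5 by 0.65 ± 0.14. Of the genes called in WT hearts Angptl4 differed by 0.29 ± 0.38 (adjusted p = 0.865), Acot1 by 0.28 ± 0.30 (adjusted p = 0.815) and Mlycd by -0.26 ± 0.13 (adjusted p = 0.513). The mean of Acot1 in KO controls lay under the brightness minimum. Glucocorticoid responsive genes (median 0.421, 1 called and 5 adjusted over the list alone) and FoxO targets (0.214) rose as lists, both at an adjusted p = 0.208 with an estimated correlation, and so did interferon genes (0.256) and lipid droplets (0.0552), both at an adjusted p = 0.588 with an estimated correlation. In total 6 genes were called, 4 up and 2 down, and 814 had an unadjusted p under 0.05. The count was 1, 2, 0, 1 and 28 without KO control replicates 1 to 5 in turn, 0 without Wy14643 replicate 2, 3 or 4, and 2 without replicate 5. It was 0 with only these groups in the fit and 98 with array weights.

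**Figure D2:**
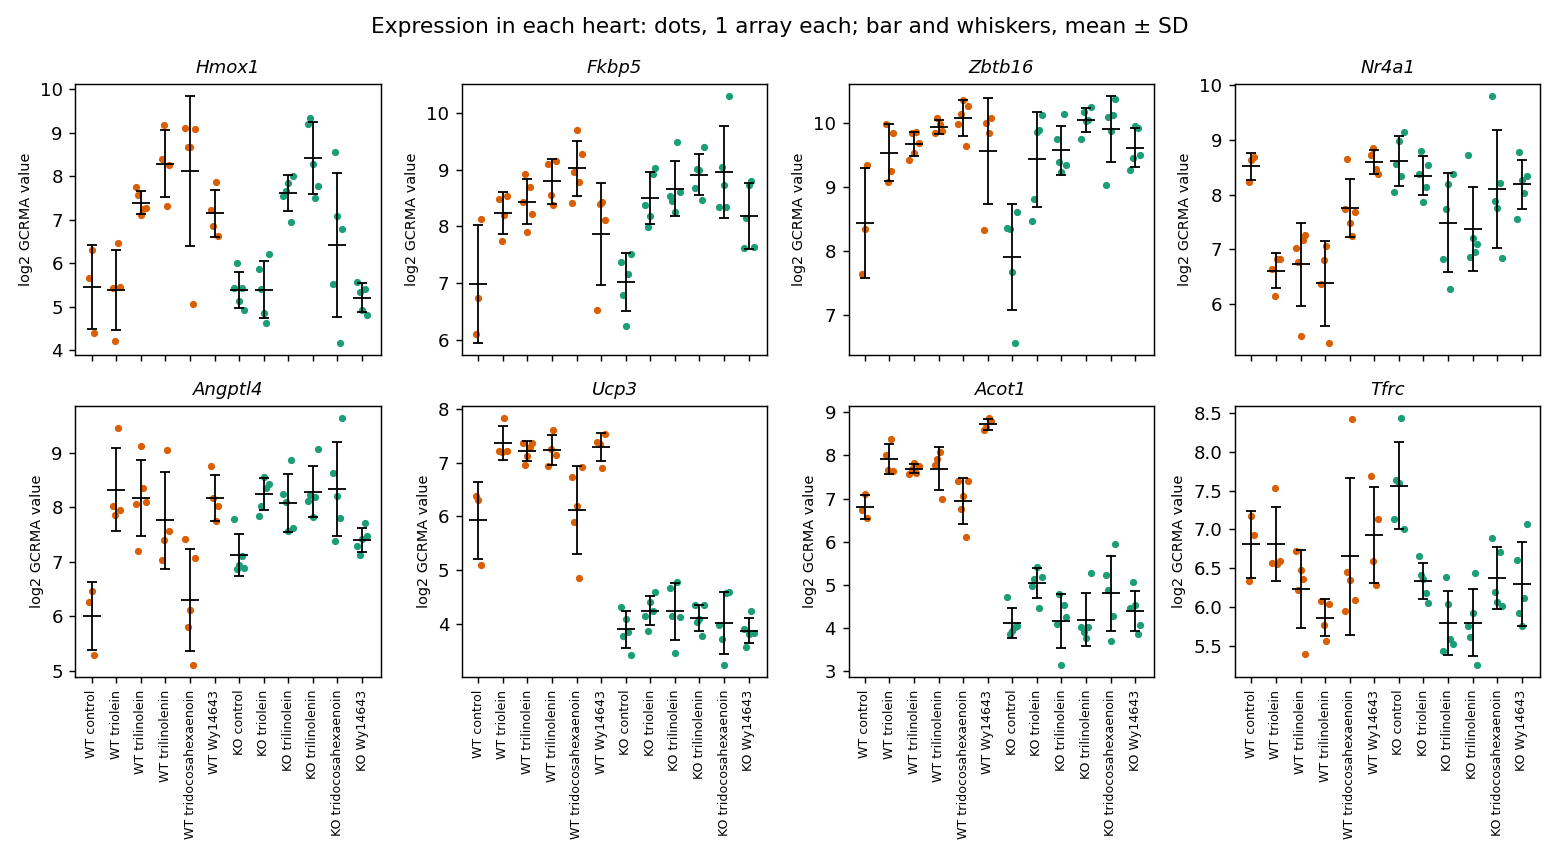
Expression of 8 genes in each heart (y axes, log2 GCRMA value) by group (x axes), with 1 dot per array and a bar and whiskers for mean ± SD. Hmox1 lies higher after trilinolein and trilinolenin in KO hearts, by 2.23 and 3.04, and Ucp3 and Acot1 lie lower in KO than in WT control hearts, by log2 differences of -2.03 and -2.67 that are not exact, since the KO means lie under the brightness minimum.

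Across the index genes, chosen before the data were examined, the treatments differed in which genes passed. Angptl4 rose after triolein, trilinolein, trilinolenin and Wy14643 in WT hearts and after trilinolenin in KO hearts. Ucp3 rose after trilinolein and trilinolenin in WT hearts, and Pdk4 rose after trilinolein, trilinolenin and tridocosahexaenoin in KO hearts. Plin2 rose after trilinolenin in WT hearts and Acot1 after Wy14643 in WT hearts. Hmgcs1, of cholesterol synthesis, fell by 0.25 ± 0.08 after trilinolein in KO hearts (adjusted p = 0.0477). Ppara, Ppard, Cpt1a, Fabp3, Cd36, Nqo1, Gclc and Srebf1 passed in no comparison of a treatment with control by limma, with log2 changes between -0.44 and 0.19 for Ppara and between -0.45 and 0.10 for Srebf1. Replicate 5 of KO trilinolenin read 6.611 for Nqo1 where the others read 7.899 to 7.948. Of the 16 index genes 14 were tested, and the others are not analysed here.

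Over the treatments of each genotype, camera with a preset correlation called 35 of the list tests in WT and 37 in KO hearts. With an estimated correlation 3 calls held in WT, PPAR targets after triolein (adjusted p = 0.00886) and Wy14643 (adjusted p = 0.00321) and FoxO targets after tridocosahexaenoin (adjusted p = 0.0473). In KO hearts 2 held, both after trilinolenin, FoxO targets (adjusted p = 0.028) and glucocorticoid responsive genes (adjusted p = 0.0497). Between the control hearts PPAR targets and mitochondrial oxidation (both adjusted p = 4.97e-08), peroxisomal lipid metabolism (adjusted p = 1.27e-05) and fatty acid synthesis (adjusted p = 0.0448) held. Of the tested members 8 of 21 lipid droplet genes, 5 of 15 glucocorticoid responsive genes, 3 of 14 FoxO genes and 1 of 22 NRF2 targets also stand in another list. In no list called against control did median, mean and test differ in sign. They did in lists that were not called, such as PPAR targets in KO hearts after trilinolenin (median -0.0284, mean 0.0965), tridocosahexaenoin (-0.00352 and 0.142) and Wy14643 (-0.00672 and 0.0377). Lists not called in any treatment comparison were those of fatty acid synthesis and desaturation (medians from -0.229 to 0.045), cholesterol synthesis (-0.162 to 0.00384), LXR targets (-0.237 to 0.101), the circadian clock (-0.132 to 0.167), hypoxia (-0.0735 to 0.0877) and fetal and stress genes of the heart (-0.16 to 0.198).

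**Figure D3:**
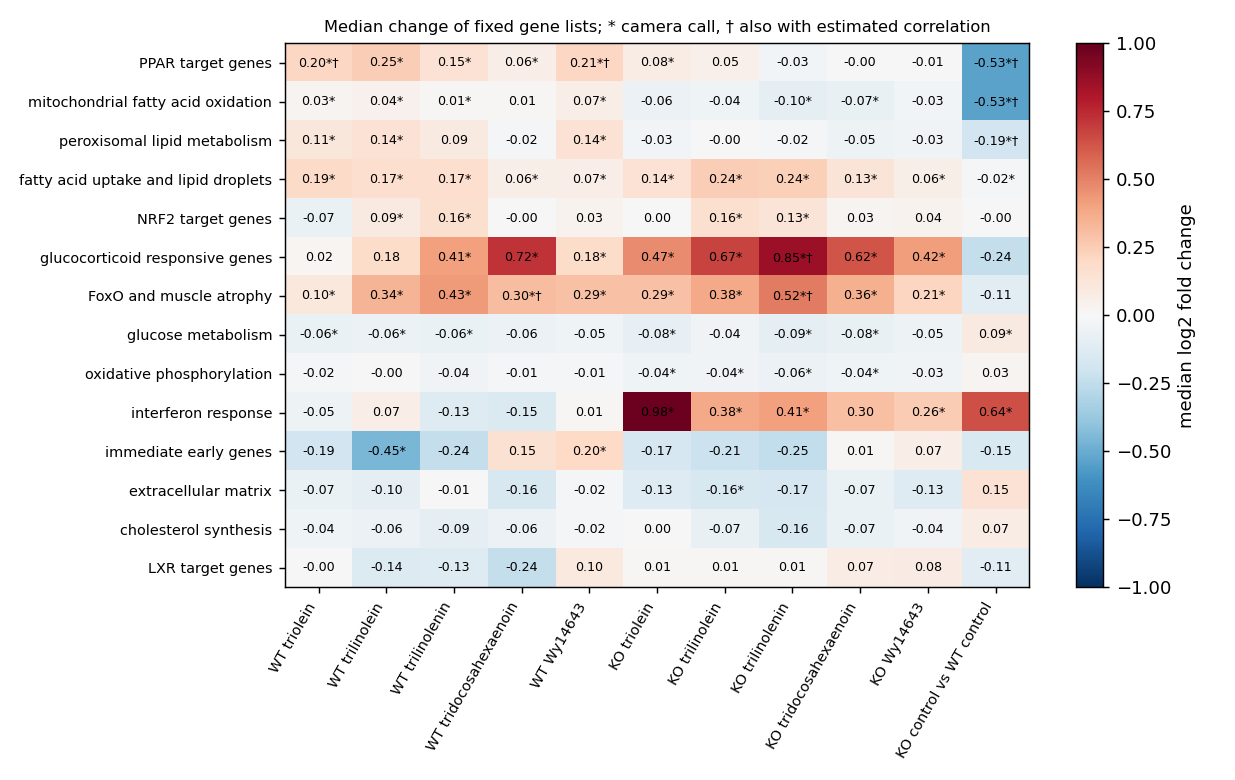
Median log2 change (colour and printed value) of 14 gene lists (y axis) in each treatment against the control of its genotype and in KO against WT controls (x axis), with * for a camera call and † for a call that holds with an estimated correlation. PPAR targets reach 0.25 in WT hearts after trilinolein and lie at -0.53 in KO against WT controls, and glucocorticoid responsive genes reach 0.85 in KO hearts after trilinolenin.

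Whether a response differed between WT and KO hearts was tested by the interaction, the change in WT minus the change in KO. Mlycd after Wy14643 came nearest to a call, with a difference of 1.04 ± 0.20 (adjusted p = 0.0517). Eci2, an enzyme of unsaturated fatty acid oxidation, followed after trilinolenin (0.37 ± 0.07, adjusted p = 0.0652). Both were named after their values were seen. Acot1 after Wy14643 differed by 1.65 ± 0.47 (adjusted p = 0.64), Angptl4 by 1.89 ± 0.60 (adjusted p = 0.794) and Ucp3 by 1.38 ± 0.42 (adjusted p = 0.64). For Acot1 and Ucp3 these sizes are not exact, because the mean in KO controls lay under the brightness minimum. Limma called 0 genes for triolein, trilinolein, trilinolenin, tridocosahexaenoin and Wy14643, with 399, 301, 383, 255 and 362 genes at an unadjusted p under 0.05 where 411.8 would by chance. With array weights, the stricter filter on dim genes or a trended and robust variance prior 1 gene each was called for trilinolenin and for Wy14643. It was 2 each with the mean of all probe sets. The trilinolenin count was 1 without KO control replicate 5 or KO trilinolenin replicate 5, and that for Wy14643 was 1 without WT Wy14643 replicate 2, KO control replicate 5 or KO Wy14643 replicate 2. PPAR targets responded more in WT than in KO hearts by camera after Wy14643 (median 0.206), trilinolenin (0.183), trilinolein (0.14) and triolein (0.0891). Their adjusted p was 0.0787, 0.123, 0.195 and 0.214 with an estimated correlation. Adjusted over the list alone 6 of 29 were called after Wy14643. For mitochondrial oxidation after trilinolenin the change in WT exceeded that in KO by 0.144 (adjusted p = 0.0845 with an estimated correlation, fry adjusted p = 0.044), with a median of 0.0125 in WT and a fall of -0.098 in KO hearts. Camera also called this list after the other treatments (0.0641 to 0.103). Peroxisomal genes were called after all but tridocosahexaenoin (0.0863 to 0.163). For glucocorticoid responsive genes the change in WT was below that in KO hearts by camera after trilinolein (median -0.433), trilinolenin (-0.432) and triolein (-0.456). The adjusted p was 0.309, 0.424 and 0.627 with an estimated correlation. Without WT control replicate 3, whose list mean was 9.06 against 8.2 and 8.56 in the other WT controls, these medians were -0.248, -0.215 and -0.163. For interferon genes after triolein the difference was -1.05 (adjusted p = 0.214 with an estimated correlation), with a median of -0.0506 in WT and 0.982 in KO hearts.

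Many calls recurred in both genotypes, which share no control arrays. After trilinolenin 163 genes were called in both with the same sign, 72 up where 5.49 would overlap by chance and 91 down where 11.9 would, among them Hmox1, Fkbp5, Zbtb16, Mt2 and Angptl4 up and Fgf16 down. After tridocosahexaenoin 59 genes were shared (29 up against 1.04 by chance, 30 down against 1.7), and after trilinolein 50 (21 up against 0.94, 29 down against 1.29). For triolein it was 1 gene, Sox18, and for Wy14643 it was 0 genes between the limma calls of 5 and 6, with 4 of the 5 WT genes having the same sign in KO hearts. No gene was called in opposite directions. Of the genes called in WT hearts 96.8% had the same sign in KO hearts after trilinolenin, 98% after tridocosahexaenoin and 99% after trilinolein. Across genes, which are not independent replicates, the changes of WT and KO correlated at 0.665 for trilinolenin, 0.653 for tridocosahexaenoin, 0.582 for trilinolein, 0.343 for triolein and 0.312 for Wy14643.

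**Figure D4:**
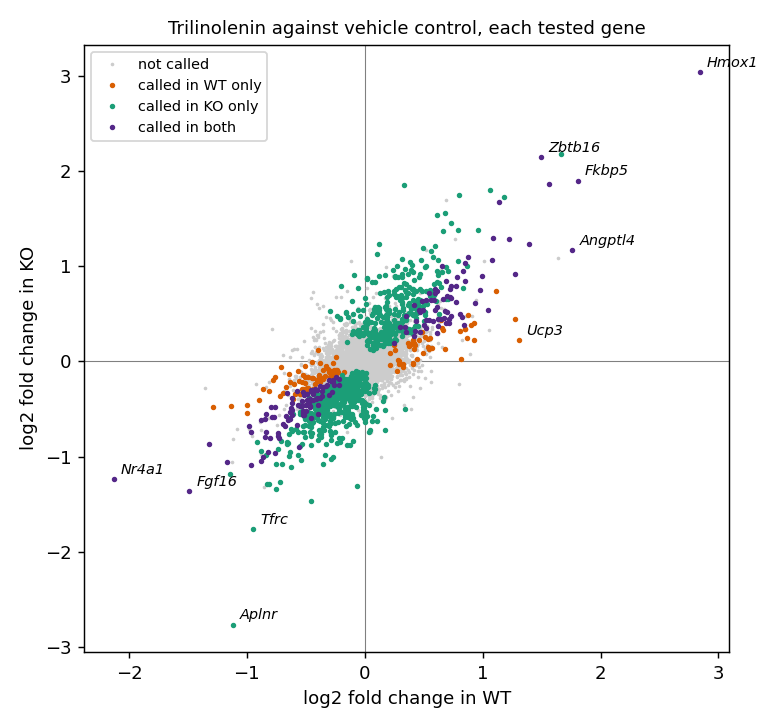
Log2 change after trilinolenin in WT hearts (x axis) and in KO hearts (y axis) for each of the 8237 tested genes, coloured by the genotype in which the gene was called. Hmox1 lies at 2.84 and 3.04, and 163 genes are called in both genotypes with the same sign.

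The triglycerides were compared with each other at the same volume and time. From triolein to trilinolein, 1 more double bond per fatty acid, WT hearts differed in 3 genes, Perm1, a muscle regulator of mitochondrial genes (-0.52 ± 0.09), Rasl11b (-0.79 ± 0.16) and Stard8 (-0.43 ± 0.09). KO hearts differed in 34 genes (16 up, 18 down), with Ptger4 (1.43 ± 0.30), Arrdc3 (0.98 ± 0.17) and Rgma (0.81 ± 0.20) higher and Adam19 (-1.61 ± 0.32), Nppb (-1.44 ± 0.31) and Lad1 (-1.11 ± 0.23) lower. From trilinolein to trilinolenin, again 1 more double bond, limma called 0 genes in either genotype, with 263 in WT and 363 in KO at an unadjusted p under 0.05. Camera called glucocorticoid (0.271 in WT, 0.246 in KO) and FoxO genes (0.136, 0.127) higher after trilinolenin. So were fetal genes in WT (0.154), and mitochondrial oxidation was lower in KO (-0.0675). Angptl4 differed there by -0.41 in WT hearts with a 95% interval from -1.23 to 0.41, and Ucp3 by 0.02 with one from -0.55 to 0.59, so differences within those bounds remain open. From triolein to trilinolenin, 2 more double bonds, 43 genes differed in WT (26 up, 17 down) and 83 in KO hearts (33 up, 50 down). Hmox1 was higher after trilinolenin by 2.90 ± 0.63 in WT and 3.02 ± 0.56 in KO hearts and Rasd1 by 1.25 ± 0.25 and 1.25 ± 0.22, while Rasl11b was lower by -0.75 ± 0.17 and -0.78 ± 0.15. Pnpla7 (1.35 ± 0.27) was higher and Alas1, the first enzyme of heme synthesis (-1.31 ± 0.25), and Adra1b (-0.80 ± 0.19) were lower in WT hearts, and in KO hearts Chac1 (1.26 ± 0.23) was higher and Adam19 (-1.72 ± 0.32) and Thap2 (-0.72 ± 0.15) were lower. The means of Rgma and Rasd1 after triolein and of Adra1b and Thap2 after trilinolenin, in the genotypes named, lay under the brightness minimum.

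Between trilinolenin and tridocosahexaenoin, which differ in chain length and in 3 double bonds, 46 genes differed in WT hearts (24 up, 22 down). Frmd5 (1.20 ± 0.20), Tnfrsf12a (1.29 ± 0.30) and Ppfia1 (1.06 ± 0.20) were higher after tridocosahexaenoin, and Ehhadh, a peroxisomal oxidation enzyme (-0.73 ± 0.17), Tspyl4 (-0.65 ± 0.15) and Hsd17b11 (-0.62 ± 0.10) were lower. Ppara itself was higher by 0.63 ± 0.12 (adjusted p = 0.00253) and Plin2 lower by -0.52 ± 0.13, and Angptl4 differed by -1.46 ± 0.41 (adjusted p = 0.0829) and Ucp3 by -1.12 ± 0.28 (adjusted p = 0.0501). PPAR targets were lower by a median of -0.0778 (2 of 29 called, 7 adjusted over the list alone, adjusted p = 0.485 with an estimated correlation). In KO hearts 27 genes differed (19 up, 8 down), with Tmprss13 (1.15 ± 0.26, its trilinolenin mean under the brightness minimum), Cish (0.88 ± 0.18) and Rasl11b (0.79 ± 0.15) higher and Zc3h6 (-0.94 ± 0.23), Arrdc3 (-0.80 ± 0.17) and Cdkn1c (-0.53 ± 0.12) lower. NRF2 targets were higher after trilinolein than triolein in WT (median 0.172) and KO hearts (0.148), and after trilinolenin than triolein (0.148 and 0.145). Their adjusted p was 0.15, 0.414, 0.122 and 0.322 with an estimated correlation. No list call between triglycerides held with an estimated correlation.

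Counts between triglycerides rested on few arrays. For trilinolein against triolein in WT hearts the count was 1 without trilinolein replicate 1, 2 or 3 or triolein replicate 1, and 0 without triolein replicate 2. In KO hearts it was 21, 17 and 21 without trilinolein replicates 1, 2 and 4, and 13 and 14 without triolein replicates 2 and 4. For trilinolenin against triolein the WT count was 13, 14 and 13 without trilinolenin replicates 2, 3 and 4, and 1 and 13 without triolein replicates 2 and 4. The KO count was 41, 37, 130 and 29 without trilinolenin replicates 1, 2, 4 and 5, and 34, 27, 49 and 41 without triolein replicates 1 to 4. For trilinolenin against trilinolein in KO hearts it was 1 without trilinolenin replicate 4. For tridocosahexaenoin against trilinolenin the WT count was 19 and 13 without trilinolenin replicates 3 and 4, and 27, 16 and 23 without tridocosahexaenoin replicates 2, 4 and 5. The KO count was 8, 1 and 14 without trilinolenin replicates 2, 3 and 5, and 0, 44, 10, 47 and 55 without tridocosahexaenoin replicates 1 to 5. It was also 0 without the 3 arrays of lowest weight.

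The treatments of 1 genotype were set against the same controls, so their changes correlate even without any effect. In WT hearts the correlation across genes had a median of 0.604 over the 10 pairs of treatments (0.389 to 0.844), against a simulated 0.598 for unchanged groups with these controls, and the covariance was 0.0229 against a simulated 0.013. The excess covariance had a median of 0.00999, and it was 0.026 between trilinolein and trilinolenin and 0.000695 between trilinolein and Wy14643. The 3 WT controls were not split, since a part would hold 1 array, and part of the excess may come from the shared controls. In KO hearts the median correlation was 0.698 (0.558 to 0.877) against a simulated 0.485, and the covariance was 0.0268 against 0.0084, an excess of 0.0184. With the 5 KO controls split in 2 and 3 arrays, the 10 splits gave median correlations from 0.331 to 0.454. 

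Markers of other cell types were followed because a heart sample can hold varying amounts of vessel or atrium. Smooth muscle markers were higher in WT hearts after triolein (median of 5 genes 0.737) and Wy14643 (0.677). They were lower in KO hearts after Wy14643 (-0.303). These were calls by camera, with no single gene called. Their adjusted p was 0.15, 0.378 and 0.447 with an estimated correlation. The interaction was 1.08 for Wy14643 (adjusted p = 0.0249 with an estimated correlation, fry adjusted p = 0.028), beside the PPAR target list of that comparison, and 1.03 for triolein (adjusted p = 0.0374 with an estimated correlation, fry adjusted p = 0.0569). Atrial muscle markers were higher after triolein in WT hearts (median 1.5, adjusted p = 0.23 with an estimated correlation), with Sln at 1.80 ± 1.08 (adjusted p = 0.824). Sln ranged from 5.08 to 11.2 over all arrays, with an SD of 1.41 within groups where the median gene had 0.167. Macrophage markers were slightly higher in KO hearts after triolein (0.205) and tridocosahexaenoin (0.14), where Cd163 rose by 0.73 ± 0.17. They were also higher in WT hearts after triolein (0.0853) and in KO against WT controls (0.203). With an estimated correlation the adjusted p was 0.45, 0.801, 0.435 and 0.401 in turn. Of 3 brown adipocyte markers Cidea was lower in KO controls, and the set had a median of -0.0688 (camera adjusted p = 0.0421, fry adjusted p = 0.00374, adjusted p = 0.209 with an estimated correlation), beside the lower genes of fat oxidation. The endothelial and fibroblast sets were not called against control, between the control hearts or in the interactions, although single members were. After trilinolein in KO hearts 2 endothelial markers rose and 2 fibroblast markers fell, and after trilinolenin 1 endothelial marker rose and 2 fell and 2 fibroblast markers fell. In WT hearts 1 endothelial marker fell after trilinolenin and 1 rose after tridocosahexaenoin. As a sign of RNA quality, the 3′ minus 5′ difference of the Actb control probe sets was 0.793 ± 0.0842 (SD, n = 3) in WT and 0.799 ± 0.0689 (n = 5) in KO controls. It was 0.593 ± 0.103 (n = 4) after trilinolenin in WT and 0.705 ± 0.0389 (n = 5) in KO hearts, the lowest means of each genotype, beside the highest gene counts. None of the 10 exact permutation tests (two-sided) against control passed after adjustment, with 0.179 the lowest adjusted p, but with 35, 56 or 252 splits no test could have passed alone.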

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

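The tests of the glucocorticoid pattern below and the look at single hearts of KO tridocosahexaenoin were chosen only after the result was seen.

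Single hearts stood apart from the rest of their group in 13 of 198 combinations of group and measure, where chance marks about 1 in 20. In WT triolein hearts replicate 3 read 7.827 for Ucp3 (others 7.19 to 7.222) and 9.461 for Angptl4 (others 7.853 to 8.023). In KO controls replicate 1 read 7.787 for Angptl4 (others 6.869 to 7.114) and 4.729 for Acot1 (others 3.854 to 4.06). Replicate 5 of KO trilinolenin read 5.266 for Acot1 (others 3.764 to 4.023) and 6.611 for Nqo1 (others 7.899 to 7.948). Plin2 read 9.409 in replicate 5 of WT trilinolein (others 9.133 to 9.211). Cpt1a read 7.209 in replicate 1 of WT trilinolenin (others 7.518 to 7.548) and 7.598 in replicate 1 of WT trilinolein (others 7.314 to 7.375). Nqo1 read 7.234 in replicate 3 of WT tridocosahexaenoin (others 7.606 to 7.758), and Srebf1 read 5.449 in replicate 4 of KO trilinolein (others 6.063 to 6.15). The Actb 3′ minus 5′ difference was 0.6044 in replicate 4 of WT triolein (others 0.703 to 0.7188), and the median correlation with the group was 0.9921 in replicate 1 of WT trilinolenin (others 0.9915 to 0.9916).

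In interactions, camera at the preset correlation and fry both singled out mitochondrial fatty acid oxidation after trilinolenin (median 0.144) and smooth muscle after Wy14643 (1.08). With an estimated correlation camera lost the first (adjusted p = 0.0845) and kept the second (adjusted p = 0.0249).

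Glucocorticoid responsive genes were higher in KO trilinolenin than in KO control hearts by a median of 0.853. Control hearts low by chance are not the whole of it. The list also differed between trilinolenin and Wy14643 hearts of KO mice by a median of 0.474 (0.407 to 0.577 without single arrays). This passed the rotation test fry, although Wy14643 itself lay 0.421 above control. RNA integrity and the time of day at collection cannot be told apart. Within groups the Actb difference correlated with the list at 0.338 in WT and -0.177 in KO hearts, so as a covariate it could remove little. The median with it was 1.05 times that without it (1.01 to 1.15 without single arrays). A clock score of 1 gene minus the mean of 6 differed by 0.0913 with a 95% interval from -0.139 to 0.381 (exact permutation p = 0.563, two-sided). A response to the fat load or to handling may account for the pattern, and neither was tested.

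PPAR target genes responded more to Wy14643 in WT than in KO hearts, by a median of 0.206 (adjusted p = 0.0787 with an estimated correlation, so the call was lost). Smooth muscle markers differed in the same comparison by a median of 1.08, and a different share of vessel in these samples was not tested as a source. Compression of dim genes in KO hearts cannot be told apart, because over the 24 of 29 members that are bright in KO controls the median was 0.164, or 0.797 of the whole, with 0.648 to 0.978 without single arrays. The 3 WT control arrays cannot be told apart as a source either, because the interaction of Wy14643 against tridocosahexaenoin, which uses no control array, had a median of 0.148 and passed the rotation test fry, but without single arrays it ran from 0.0972 to 0.176. The loss of PPARα is the biological explanation the design offers, and it stays open with the substrain.

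Genes differing between KO and WT controls could come from the donor-strain stretch of chromosome that stays around the targeted gene. Of the called genes 1.01% (upper 95% bound 2.91%) lay among the 100 tested genes nearest Ppara, and 3% of those near against 3.61% of the rest were called (Fisher's exact p = 0.705, one-sided). Genes this near were not called more often. As 100 could not be most of 298 calls, a longer stretch was not tested. Substrain and deletion go together in every sample, so their shares cannot be told apart.

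Other splits of the same arrays were counted, the real split included. The shares were not adjusted over the comparisons, so one under 0.05 argues against chance only for a comparison taken alone. The counts with as many called genes as the real split were 1 of 35 for triolein in WT hearts (real 6, highest other 3), 1 of 56 for trilinolein (103, 4), 1 of 35 for trilinolenin (281, 19) and 2 of 56 for tridocosahexaenoin (153, 191), each a share under 0.05. For Wy14643 in WT hearts 3 of 35 splits did (5, 12), so chance cannot be excluded. In KO hearts the counts were 2 of 100 for triolein (95, 120), 1 of 100 for trilinolein (356, 85), 1 of 100 for trilinolenin (984, 584), 3 of 100 for tridocosahexaenoin (292, 337) and 3 of 100 for Wy14643 (6, 13), each a share under 0.05. For KO against WT controls it was 1 of 56 (298, 61), also a share under 0.05.

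For the interactions, where the real count was 0, 100 of 100 splits did as well, and the highest other counts were 7 for triolein, 7 for trilinolein, 4 for trilinolenin, 515 for tridocosahexaenoin and 2 for Wy14643. Between triglycerides in WT hearts the counts were 2 of 100 for trilinolein against triolein (3, 3), 1 of 35 for trilinolenin against triolein (43, 2) and 1 of 100 for tridocosahexaenoin against trilinolenin (46, 34), each a share under 0.05 without adjustment. In KO hearts they were 1 of 100 for trilinolein against triolein (34, 1) and 1 of 100 for trilinolenin against triolein (83, 42), likewise under 0.05 without adjustment. For trilinolenin against trilinolein 100 of 100 splits gave as many as the real 0 in each genotype, with highest others of 5 in WT and 24 in KO. For tridocosahexaenoin against trilinolenin in KO hearts 8 of 100 did (27, 182), so chance cannot be excluded. The 182 is several times the real 27, and the 515 arose where the real count was 0. What gave such splits was not tested. In KO tridocosahexaenoin hearts the heat shock mean was 10.859 in replicate 1 and 8.886 to 9.158 in the others. The glucocorticoid mean was 9.998 in replicate 5 and 8.6 to 9.109 in the others. These hearts had the lowest correlations within that group, 0.982 and 0.983. The highest other split also exceeded the real count for tridocosahexaenoin and Wy14643 in WT hearts and for triolein, tridocosahexaenoin and Wy14643 in KO hearts, and wherever the real count was 0, with the values given above.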

How the results depend on the processing

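The fit without the 3 arrays of lowest weight was chosen after the weights were seen. Only 45.28% of genes rose above the background chosen here, so changes in dim genes are not covered, and the WT comparisons rest on 3 control arrays. Where a value below differs from the report, the cause was not tested unless the setting itself tests fewer genes or arrays. No call of a named gene turned in sign, but differences that were not called did so without single arrays, among them Angptl4 and Ucp3 after tridocosahexaenoin in WT hearts. Of 2254 alternatives of the 257 calls of named genes, other than leaving out arrays, 1995 kept the call and 259 lost it, and of 2265 with an array left out 1618 kept it and 647 lost it. Over all alternatives, left-out arrays included, the call of Fam107a after Wy14643 in KO hearts was lost in 13 of 19, that of Cpt2 after trilinolein in WT hearts in 11 of 17 and that of Angptl4 after Wy14643 in WT hearts in 8 of 16. With Spearman correlation the median similarity was 0.579 in WT and 0.62 in KO hearts, and with camera on a trended fit the list calls were 37 and 42. Of 99 named calls with another bright probe set 1, that of Pigo in KO against WT controls, had one of opposite sign.

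With no filter on dim genes 14 of 33 results moved by over 1.5 times. The counts were 43 for WT trilinolein, 180 for WT trilinolenin, 56 for WT tridocosahexaenoin, 26 for KO triolein, 213 for KO trilinolein and 1 for KO Wy14643. Between triglycerides they were 1 for WT trilinolein against triolein, 10 for WT and 49 for KO trilinolenin against triolein and 6 for KO tridocosahexaenoin against trilinolenin. The overlaps of WT and KO calls were 0 for triolein, 23 for trilinolein, 98 for trilinolenin and 21 for tridocosahexaenoin.

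With the stricter filter 6 of 28 moved, to 10 for WT triolein, 15 for WT Wy14643, 1 each for the trilinolenin and Wy14643 interactions, 6 for WT trilinolein against triolein and 70 for WT trilinolenin against triolein. With the mean of probe sets 7 of 33 moved, to 13 for WT Wy14643, 3 for KO Wy14643, 2 each for the trilinolenin and Wy14643 interactions, 6 for WT trilinolein against triolein, 72 for WT trilinolenin against triolein and 2 for the triolein overlap. With quantile normalization again 3 of 28 moved, to 10 for WT triolein, 14 for WT Wy14643 and 66 for WT trilinolenin against triolein. With the trend and robust prior 5 of 29 moved, to 14 for WT Wy14643, 1 each for the trilinolenin and Wy14643 interactions, 5 for WT trilinolein against triolein and 2 for the triolein overlap.

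With array weights 14 of 24 moved. The counts were 3, 299, 477, 411 and 41 for triolein, trilinolein, trilinolenin, tridocosahexaenoin and Wy14643 in WT hearts. In KO hearts they were 391 for triolein, 549 for trilinolein and 98 for Wy14643. They were 1 each for the trilinolenin and Wy14643 interactions, 28 for WT and 148 for KO trilinolenin against triolein, 118 for KO trilinolein against triolein and 0 for KO tridocosahexaenoin against trilinolenin. Without the arrays of low weight 8 of 24 moved, to 155 for WT trilinolein, 11 for WT Wy14643, 93 for KO tridocosahexaenoin, 1 for the trilinolenin interaction, 6 for WT and 75 for KO trilinolein against triolein, 109 for WT trilinolenin against triolein and 0 for KO tridocosahexaenoin against trilinolenin.

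With only the groups compared 14 of 24 moved. The counts were 65, 137 and 13 for trilinolein, trilinolenin and tridocosahexaenoin in WT hearts, 31, 633, 12 and 0 for triolein, trilinolenin, tridocosahexaenoin and Wy14643 in KO hearts, and 190 for KO against WT controls. Between triglycerides they were 0 for WT and 19 for KO trilinolein against triolein, 17 for WT and 33 for KO trilinolenin against triolein, and 0 each for WT and KO tridocosahexaenoin against trilinolenin. Averaged over all treatments KO and WT differed in 3211 genes, 212 of them by over 1.5-fold. With an estimated correlation the list calls were 3 in WT and 2 in KO hearts, and with fry they were 11 in WT hearts.

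Replicate numbers do not pair the samples, since the residuals of 40 pairs of a treated and a control array with the same number correlated at -0.234 to 0.231. With a replicate block 5 of 33 results moved, to 98 for WT tridocosahexaenoin, 9 for WT Wy14643, 5 for WT trilinolein against triolein, 67 for WT trilinolenin against triolein and 2 for the triolein overlap.

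With each array left out in turn, the counts in WT hearts ran from 0 to 10 for triolein, 16 to 105 for trilinolein, 46 to 205 for trilinolenin, 0 to 250 for tridocosahexaenoin and 0 to 16 for Wy14643. In KO hearts they ran from 4 to 201, 100 to 343, 649 to 1071, 43 to 505 and 0 to 28 in the same order, and for KO against WT controls from 193 to 286. The interactions ran from 0 to 1 for trilinolenin and Wy14643 and stayed at 0 for triolein, trilinolein and tridocosahexaenoin. Between triglycerides in WT hearts the ranges were 0 to 4 for trilinolein against triolein, 1 to 58 for trilinolenin against triolein and 13 to 59 for tridocosahexaenoin against trilinolenin, with 0 throughout for trilinolenin against trilinolein. In KO hearts they were 13 to 44, 27 to 130 and 0 to 55, with 0 to 1 for trilinolenin against trilinolein. List calls ran from 28 to 38 in WT and 33 to 40 in KO hearts, and the median correlation between treatments from 0.62 to 0.695 and from 0.676 to 0.741. The arrays behind these moves of the counts are named in the report. After the data were seen, the median of each list or marker set called by camera was also taken without each array. Of 145 such medians 76 stayed within 1.5 times throughout, 69 moved further and 5 of these turned in sign. The 5 were mitochondrial oxidation after triolein, trilinolein and trilinolenin in WT hearts, the unfolded protein response after tridocosahexaenoin in KO hearts and immediate early genes in the tridocosahexaenoin interaction (0.185, and -0.0415 without WT control replicate 1).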

Other observations

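The test of variation within groups was chosen only after the result was seen.

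Hearts of the same group varied along a common axis. The first principal component of the deviations from group means, computed without the glucocorticoid list, held 10.5% of the variance. Among the 10 named genes of largest weight in each direction, Tinagl1 followed it at a correlation of 0.904, Trp53inp1 at 0.754, Setdb2 at 0.74 and Sox17 at 0.73. Nrep (-0.871), Aplnr (-0.864), S1pr3 (-0.8) and Sox4 (-0.797) ran against it. Setdb2, Aplnr, Sox4, Fgf16 (-0.747) and Tfrc (-0.643) are also among the largest KO trilinolenin changes named, as Nrep and S1pr3 are for KO tridocosahexaenoin.

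Variation in glucocorticoid signalling between animals may lie behind this axis. Its correlation with the mean of the glucocorticoid responsive genes was 0.749 in 25 WT arrays (permutation p = 2e-05, adjusted p = 8e-05 over 8 relations, rho 0.766 with p = 8e-05, 0.755 without the 2 farthest arrays). In 30 KO arrays it was 0.871 (permutation p = 1e-05, the smallest that 1e+05 permutations can give, adjusted p = 8e-05, rho 0.892, 0.823 without the 2 farthest). The Actb difference (0.338 in WT, adjusted p = 0.32, and -0.177 in KO, adjusted p = 0.34, by permutation) did not pass. Atrial markers (-0.193, adjusted p = 0.4, and 0.454, adjusted p = 0.06, by permutation) did not pass by Pearson correlation, but in KO hearts they passed by Spearman's rho (0.473, permutation adjusted p = 0.04). The interferon list passed in WT hearts (-0.545, permutation adjusted p = 0.027) and not in KO hearts (0.239, adjusted p = 0.34), but the list means of the WT arrays, 4.14 to 4.6, lay around the brightness minimum. Hormone levels were not analysed here, so the hypothesis rests on transcripts alone.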
